A study of Caenorhabditis elegans with 4 samples.

How the data were processed

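The samples were 4 poly(A) RNA libraries of whole gravid adults, 2 of the wild-type strain N2 and 2 of the rde-3 mutant strain YY1449, called biological replicates in the series' design text. Per the labels, total RNA was extracted with TRIzol, mRNA was purified in 2 rounds on oligo(dT) beads, cDNA was made in separate first- and second-strand steps, and libraries were made with the Nextera XT kit, which keeps no record of the RNA strand. The submitters' processing notes name Trim Galore 0.4.4, cutadapt 1.14, STAR 2.7.0a and SAMtools 1.3.1 and the genome builds ce11 and WBcel235. The counting tool, its treatment of reads that match several places, the statistical model and its version are not given in the sources used here.

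The authors deposited 2 tables of their own comparison. The larger one holds 18638 features, 18468 genes and 170 repeat elements named by element, family and class, and the smaller one was found to hold exactly the 3254 features with an adjusted p under 0.05. Per the file headers each table has 6 columns of values. The signal column of the deposited tables is a mean over the libraries of counts divided by size factors, read from its name and its values. The deposited log2 column is the log2 fold change, taken as mutant over wild type from the order in which the comparison is named. The other value column of the deposited tables is the standard error of that log2 fold change. The deposited score column is the Wald statistic, and it equalled log2 fold change over standard error to within 1.1e-13. The deposited p-value column equalled the two-sided normal p of that statistic to within 2.7e-15, and the adjusted p-value column equalled the Benjamini-Hochberg adjustment over all 18638 features to within 1.9e-15. All counts of genes and repeats use the authors' deposited adjusted p at 0.05. Because no values per library were used, no model of counts was fitted and no library was left out in turn. The p-values rest on the deposited standard errors, from 2 libraries per group. How those errors were estimated, and whether they draw on a spread shared across genes, is not known.

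The depth of each library is unknown. Its relative size could be read from the lowest mean values: all 3528 features with a mean under 3 were whole multiples of 4 steps (tolerance 1e-08; 0 after random offsets). The steps give size factors of 1.42 and 0.963 for libraries whose reads go with negative log2 values and 1.06 and 0.707 for libraries whose reads go with positive ones. These were used only to find genes with 0 to 3 reads in a group. For those with 0 reads the change is given as a bound against a floor of 3 reads over the group, counting error only, and 15 of the higher and 13 of the lower genes were of this kind. For named genes with 1 to 3 reads in a group the ratio has a 95% counting interval, from an exact Clopper-Pearson interval of the mutant share of the reads implied by the deposited mean and fold change, rounded to whole reads. The mean normalized counts summed to 21685102, of which 4 ribosomal RNA genes held 28.6%, the vitellogenins 8.18%, the mitochondrial protein genes 1.25% and the repeats 0.159%. The median standard error of log2 was 0.608 for genes with means of 10 to 100, 0.216 for 100 to 1000, and 0.135 for 1000 and above, and the smallest absolute log2 change called was 0.31. In simulated data with the same standard errors, 62 of 100 features changed by log2 of 1 and 80 of 100 changed by log2 of 2 were called, and 6 of 18438 unchanged ones. The simulation took those errors as exact, with normal noise, and changed only genes with a mean of at least 10. Far fewer features were changed than were called in the data. Its rates therefore need not hold for the data and do not test the errors. Of 12436 features with a mean of at least 10, 26 had values identical to those of another feature.

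Gene names were matched to the Ensembl release 115 annotation of WBcel235 for 18289 genes, and 179 genes were not matched. Coordinates are from that annotation. Gene lists were fixed before the data were examined: small RNA machinery, Argonautes, recalled ERGO-1 targets, histones, major sperm proteins, spermatogenesis, oocyte, germline, vitellogenins, early embryo, male soma, intracellular pathogen response, innate immunity, heat shock, organelle stress, detoxification, collagens, neurons, neuropeptides, muscle, intestine, ribosomal proteins, mitochondrial genome and DNA damage. These 24 lists and the 7 repeat classes with at least 3 members were tested with camera (cameraPR in limma 3.58.1, R 4.3.3) on the deposited Wald statistics, two-sided, with an assumed correlation of 0.01 between members and Benjamini-Hochberg adjustment over the 31 sets. X-linked and autosomal genes were compared with Fisher's exact test, two-sided, in scipy 1.17.1 under Python 3.11.15. Named genes follow a rule fixed before the data were examined: mut-2, the 8 largest rises and falls among called genes with a mean of at least 50, the 4 smallest adjusted p in each direction, the 8 largest rises and 4 largest falls among called repeats with a mean of at least 10, Tc1, Tc3, Tc4 and Tc5, and up to 3 members per list of smallest adjusted p. The gene unc-45 was named after its value was seen.

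The length of a gene is that of its longest annotated transcript, known for 99.0% of the 8998 genes with a mean of at least 50. The length trend was a lowess fit of log2 fold change on log2 length over those genes with a span of 0.3, and after its subtraction the Wald test was recomputed with the deposited standard error. Alternatives were adjusted p thresholds of 0.01 and 0.1, a minimum absolute log2 change of 1, a minimum mean of 10, separate adjustment of genes and repeats, log2 values recentred on the median of 7656 genes with a mean of at least 100 (a shift of 0.05), a t distribution with 2 degrees of freedom, a camera correlation of 0.05 and camera on ranks. Added after the data were seen were the removal of the length trend and the removal of the left end of chromosome X, up to the gene set-28 at 215588, where the low values ended.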

Results

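Poly(A)-selected RNA from whole gravid adult Caenorhabditis elegans was sequenced in 4 libraries, 2 from N2, the standard laboratory wild type, and 2 from YY1449, a strain mutant for rde-3. The gene rde-3, also named mut-2, encodes a nucleotidyltransferase that adds poly(UG) tails to RNAs and is needed for RNA interference and for the silencing of transposons. The comparison asked which genes and which repeat elements differed in RNA level between the mutant and the wild-type animals. The authors' deposited table listed 18638 features, of which 18468 were genes and 170 were repeat elements, each with a mean normalized count over the 4 libraries, a log2 fold change and its standard error. No values per library were analysed here, so the read depth of each library is unknown and no spread between the 2 replicates of a group can be shown. Errors below are the standard errors of that table, and its adjusted p was used at a threshold of 0.05. Positive log2 values were read as higher in the mutants from the order in which the comparison is named, since the table itself does not state the direction.

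The RNA level of the mutated gene itself differed by less than its error. In the authors' deposited table mut-2 (chromosome I, 6356614 to 6358411, build WBcel235) had a mean normalized count of 780.4 and a log2 fold change of 0.06 ± 0.16 (adjusted p = 0.905). The labels name no allele, so the RNA of mut-2 need not fall in the mutants, and its value does not check the direction of the comparison.

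Many genes changed in the rde-3 mutants, in both directions. Each genotype came from a single strain, so an effect of rde-3 cannot be told apart from other differences between YY1449 and N2, for genes and repeats alike. By the authors' deposited table, the RNA of 1737 genes was higher and that of 1497 was lower, together 17.5% of the 18468 genes, and their median absolute log2 change was 0.76. A change of at least 2-fold was seen in 530 of the genes that were higher and in 631 of those that were lower. These calls rest on a normal distribution of the deposited test statistic. Against a t distribution with 2 degrees of freedom 0 genes and 0 repeats passed (smallest adjusted p = 0.682). The unadjusted p was then under 0.05 for 622 higher and 501 lower genes and for 12 and 2 repeats. If none of the 18638 features had changed, a share of 0.05 of them would be expected under that threshold, so these counts lend those genes little support. The absence of adjusted calls follows from the heavy tails of that distribution over 18638 tests, so it cannot decide which calls hold. Among the strongest changes were uncharacterised genes that were nearly silent in the wild type, sperm genes, which were lower, and several families of transposons, which were higher.

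The genes with the largest rises had few reads in wild-type animals. F15D4.5 (chromosome II, 13245376 to 13247774) rose 370-fold (log2 8.53 ± 0.33, adjusted p = 1.7e-141), the smallest adjusted p in the authors' deposited table. C38D9.2 (chromosome V, 17567150 to 17571742) rose 765-fold (log2 9.58 ± 0.54) and Y47H10A.5 (chromosome I, 12095482 to 12097987) rose 400.2-fold (log2 8.64 ± 0.72) in the authors' deposited table. F11D11.3 (chromosome V, 18757924 to 18760274) had a log2 value of 11.005 ± 1.47 in the authors' deposited table, which puts its wild-type mean at 0.158 normalized counts, below the 0.353 that a single read would give. Against a floor of 3 reads over the wild-type group it was at least 258-fold higher. For F55B11.6 and ZC15.3 the deposited values imply about 1 and 3 reads over the wild-type group, so their ratios in the authors' deposited table, 315 (95% counting interval 56.2 to 12537) and 234 (75.2 to 1076), are poorly determined. The piRNA loci 21ur-10687 and 21ur-10492, listed at log2 8.76 ± 1.42 and 8.71 ± 1.05 in the authors' deposited table, had about 1 and 2 wild-type reads and lie inside F15D4.5 on its opposite strand, and the library kit does not mark strand, so their reads cannot be told apart from those of F15D4.5. With smaller folds, tbb-6, a beta-tubulin gene, rose 29.03-fold (log2 4.86 ± 0.27) and lea-1, which encodes a late embryogenesis abundant protein linked to desiccation tolerance, rose 4.56-fold (log2 2.19 ± 0.12) in the authors' deposited table.

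The largest falls were in the pud genes, sperm genes and genes at the left end of chromosome X. The authors' deposited table gave pud-2.1 (chromosome V, 2329444 to 2329954) a log2 value of -9.85 ± 1.49, with a mutant mean of 0.212 normalized counts, below the 0.473 of a single read, so that it was at least 115.4-fold lower against a floor of 3 reads over the mutant group. The pud genes lie in a cluster of near-identical copies, so the division of reads between copies is uncertain. The nearby gene pud-3 fell by 3.91 ± 0.46 on the log2 scale, and clec-218, which encodes a C-type lectin, fell by 3.58 ± 0.28 in the authors' deposited table. Y73B3A.1 (chromosome X, 42632 to 46933) fell by 5.92 ± 0.66 and Y73B3A.4 (chromosome X, 95614 to 104777) fell by 3.59 ± 0.43 in the authors' deposited table. Among 16822 overlapping windows of 20 neighbouring genes with a mean of at least 1, the lowest median log2 value (-3.14) was at 78429 to 215588 on chromosome X, and the lowest away from that end was on chromosome IV (4999485 to 5069861, -2.72). The smallest adjusted p among the falls belonged to fat-7, a stearoyl-CoA desaturase gene of the intestine, which was 10.7-fold lower (log2 -3.42 ± 0.16, adjusted p = 1.4e-94) in the authors' deposited table. Next came the muscle genes tnt-2 and dim-1 and the calponin-like gene clik-1, with log2 values of -1.96 ± 0.12, -2.004 ± 0.13 and -1.74 ± 0.11 in the authors' deposited table.

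Transposons were higher in the mutants far more often than lower. Of the 170 repeat elements in the authors' deposited table, 18 were higher and 2 were lower, and 14 of the 18 rose at least 2-fold. The LTR retrotransposons CER3 (internal part, log2 3.56 ± 0.45) and CER9 (internal part, log2 3.16 ± 0.14, adjusted p = 1.6e-108) rose 11.8-fold and 8.91-fold in the authors' deposited table. Among DNA transposons, Tc5 rose 6.93-fold (log2 2.79 ± 0.31), MIRAGE1 rose 6.76-fold (log2 2.76 ± 0.16), Tc1 rose 5.27-fold (log2 2.398 ± 0.32) and Tc4 rose 4.75-fold (log2 2.25 ± 0.21) in the authors' deposited table. Chapaev-2 and CEMUDR1 also rose, by log2 2.04 ± 0.27 and 2.02 ± 0.16 in the authors' deposited table. Tc3, of the same superfamily as Tc1, had a log2 value of 0.22 ± 0.27 (adjusted p = 0.751) in the authors' deposited table, a difference within its error. The 2 elements that fell in the authors' deposited table were the SINE CELE45 (log2 -1.82 ± 0.13) and the LTR retrotransposon CER17 (internal part, log2 -0.99 ± 0.20).

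By class, 9 of 86 DNA transposons were higher and none was lower, and 6 of 38 LTR elements were higher and 1 was lower in the authors' deposited table. With limma's camera test on the deposited test statistics, both classes stood above all other features (adjusted p = 0.00141 for DNA transposons and 0.00144 for LTR elements), as did the 7 Helitrons (adjusted p = 0.0419), of which 1 was higher. None of the 13 LINE elements and 1 of the 13 satellites was higher, and neither class passed (camera adjusted p = 0.619 and 0.212). The 7 elements of unknown class and the 4 of uncertain DNA class did not pass either (camera adjusted p = 0.619 and 0.306). No correlation between members of a set could be estimated, because no values per library were used, and the camera tests assumed 0.01. At an assumed correlation of 0.05 the calls for DNA transposons (adjusted p = 0.0962) and Helitrons (adjusted p = 0.0844) were lost.

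**Figure D1:**
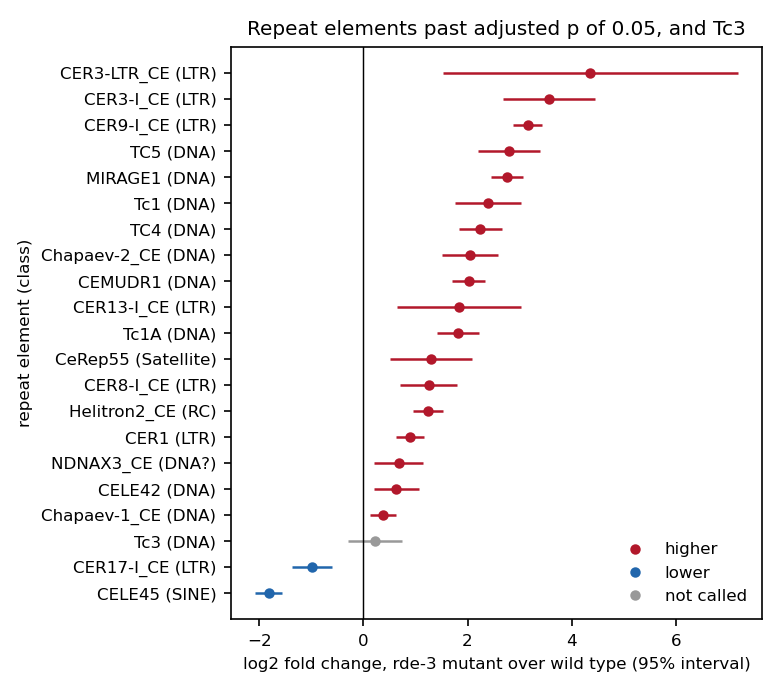
Log2 fold change (rde-3 mutant over wild type, horizontal axis) of the 20 repeat elements past an adjusted p of 0.05 and of Tc3, with points for the values and bars for 95% intervals from the standard errors in the authors' deposited table. The class of each element is in brackets, and 18 elements lie above 0, 2 lie below, and the interval of Tc3 includes 0.

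Sperm genes were lower as a group. Of 37 genes for major sperm proteins, the cytoskeletal proteins of nematode sperm, 30 were lower, both over all features and adjusted over the list alone, and none was higher in the authors' deposited table. Their median log2 value was -2.87, a 7.30-fold lower level (camera adjusted p = 1.8e-40), with msp-76 at -3.08 ± 0.29 and msp-59 at -3.13 ± 0.33 in the authors' deposited table. Msp genes are near-identical copies, so the value of each single gene is uncertain. Their values may also depend on each other, so the 30 lower genes need not be separate observations. The camera test assumed a low correlation between members, so its p for this list may be far too small. At an assumed correlation of 0.05 the camera adjusted p of this list was 5.8e-20, and the true correlation is unknown. Among 46 other spermatogenesis genes 22 were lower and 1 was higher (23 and 1 adjusted over the list alone), with a median log2 value of -2.07 (camera adjusted p = 2.1e-09). With the 5 members that had no reads in a group set at their bound, that median was -1.79. The fallen members included sss-1 at log2 -3.30 ± 0.33 and nspd-1 at -2.49 ± 0.40 in the authors' deposited table.

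Oocyte genes moved the other way. Of 29 genes of oocytes and the eggshell, 23 were higher and none was lower (25 and 0 adjusted over the list alone), with a median log2 value of 0.47, or 1.39-fold (camera adjusted p = 4.3e-12). They included cav-1, a caveolin gene (log2 1.53 ± 0.21), cpg-2, an eggshell chondroitin proteoglycan gene (0.75 ± 0.12), and puf-3, which encodes an RNA-binding protein of oocytes (0.57 ± 0.12), in the authors' deposited table. Of 28 genes of the mitotic and meiotic germline and P granules, 7 were higher and 7 were lower (8 and 12 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.540). Its members went both ways, with glh-2 at log2 0.81 ± 0.13 and fbf-2 at -1.14 ± 0.18 in the authors' deposited table. Of 25 early zygotic embryo genes only tbx-11 passed, at log2 1.73 ± 0.49 in the authors' deposited table (camera adjusted p = 0.306 for the list). Of 9 genes of male somatic tissues only gem-4 passed, at log2 1.203 ± 0.26 in the authors' deposited table (camera adjusted p = 0.619).

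Muscle genes were lower, and the neuronal list did not pass. Of 28 genes of body wall and pharyngeal muscle, 20 were lower and 1, the myosin chaperone gene unc-45, was higher (22 and 1 adjusted over the list alone). The median log2 value of the muscle list was -1.03, a 2.05-fold lower level (camera adjusted p = 8.7e-57). The troponin T genes tnt-2 and mup-2 had log2 values of -1.96 ± 0.12 and -1.98 ± 0.13 in the authors' deposited table. Of 28 neuronal and synaptic genes 1 passed and none was lower (0 and 0 adjusted over the list alone). That gene, unc-11, had a log2 value of 0.35 ± 0.13 in the authors' deposited table, and the list did not pass (camera adjusted p = 0.619). The call for unc-11 was lost after recentring of the log2 values on the median of abundant genes (adjusted p = 0.109) and after removal of a trend with transcript length (adjusted p = 0.552). Among 129 neuropeptide genes 2 were higher and 3 were lower (0 and 2 adjusted over the list alone; camera adjusted p = 0.634), with nlp-24 at log2 -1.09 ± 0.21 in the authors' deposited table.

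Intestine genes split. Of 26 intestine genes other than those for yolk proteins 8 were higher and 5 were lower (10 and 5 adjusted over the list alone; camera adjusted p = 0.515). The cathepsin gene cpr-1 (log2 1.28 ± 0.11) and the P-glycoprotein gene pgp-1 (1.79 ± 0.17) rose and fat-7 fell in the authors' deposited table. Of the 6 vitellogenin genes, which encode yolk proteins, vit-2 (log2 -0.90 ± 0.15) and vit-1 (-1.54 ± 0.33) fell and vit-6 (0.41 ± 0.14) rose in the authors' deposited table (camera adjusted p = 0.122). The call for vit-6 was lost after recentring (adjusted p = 0.0554) and after removal of the length trend (log2 0.11, adjusted p = 0.775). Among 179 detoxification genes 26 were higher and 12 were lower (26 and 13 adjusted over the list alone; camera adjusted p = 0.255), with ugt-62 at log2 1.86 ± 0.12, gst-38 at 3.02 ± 0.38 and cyp-35C1 at -1.88 ± 0.22 in the authors' deposited table.

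Genes for antimicrobial effectors were higher. Of 30 innate immunity genes 8 were higher and 2 were lower (9 and 2 adjusted over the list alone), with a median log2 value of 0.96 (camera adjusted p = 3.5e-05). The lysozyme genes lys-1 (log2 1.94 ± 0.11) and lys-8 (0.89 ± 0.14) and the C-type lectin gene clec-67 (1.63 ± 0.24) rose in the authors' deposited table. Of 39 genes of the intracellular pathogen response 5 were higher and none was lower, but the list did not pass (camera adjusted p = 0.306). Its risen members included skr-4 (log2 2.11 ± 0.34) and pals-23 (1.70 ± 0.30) in the authors' deposited table. Of 17 cytosolic heat shock genes 2 were higher (camera adjusted p = 0.306), the small heat shock protein gene sip-1 at log2 1.05 ± 0.12 and hsf-1 at 0.45 ± 0.14 in the authors' deposited table. The call for hsf-1 was lost after removal of the length trend (log2 0.295, adjusted p = 0.166). Of 19 genes of the endoplasmic reticulum and mitochondrial stress responses 6 were higher and 1 was lower (camera adjusted p = 0.122), with pdi-3 at log2 0.62 ± 0.12 and crt-1 at 0.51 ± 0.11 in the authors' deposited table.

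Genes of the small RNA pathways changed in part. Of 36 genes for the mutator complex, siRNA amplification and RNA interference 13 were higher and 1 was lower (16 and 1 adjusted over the list alone), with a median log2 value of 0.31 (camera adjusted p = 3.2e-05). After removal of the length trend 6 were higher and 1 was lower (camera adjusted p = 0.0190). The Dicer gene dcr-1 (log2 0.82 ± 0.13) and sid-2, needed for uptake of double-stranded RNA from the gut (1.599 ± 0.24), rose, and the helicase gene eri-7 fell (-2.42 ± 0.21) in the authors' deposited table. Of 22 Argonaute genes 5 were higher and 4 were lower (camera adjusted p = 0.587), with ergo-1 at log2 0.77 ± 0.12, wago-2 at 1.07 ± 0.17 and wago-4 at -1.27 ± 0.15 in the authors' deposited table. Of 10 genes recalled as targets of ERGO-1 class siRNAs 2 were higher, E01G4.5 (log2 1.37 ± 0.27) and W04B5.1 (1.45 ± 0.52) in the authors' deposited table, and the list did not pass (camera adjusted p = 0.122).

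Of 24 genes of DNA double-strand break repair, checkpoints and apoptosis 11 were higher and 1 was lower (14 and 1 adjusted over the list alone), with a median log2 value of 0.41 (camera adjusted p = 3.5e-05). After removal of the length trend 7 were higher and 1 was lower (camera adjusted p = 0.00402). The repair genes rad-50 (log2 1.32 ± 0.13) and polq-1 (0.81 ± 0.15) and the caspase gene ced-3 (0.65 ± 0.13) rose in the authors' deposited table. Of 67 histone genes 4 were higher and 2 were lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.515), and the members of smallest adjusted p were linker histone genes, his-24 (log2 2.21 ± 0.26), hil-5 (-1.12 ± 0.15) and hil-3 (1.99 ± 0.35) in the authors' deposited table. Selection for poly(A) RNA leaves out histone RNAs that lack a poly(A) tail, so the histone counts do not cover those. A group without reads was implied for 6 of the 67 histone genes. Of 160 cuticle collagen genes 14 were higher and 32 were lower (15 and 32 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0663). The camera direction was down and the median log2 value was -0.04, whereas the mean was 0.13. The 141 members named col had 32 lower and 8 higher genes, and this family was rich in lower genes in a test chosen later (below). Members of the list went both ways, as dpy-17 (log2 2.95 ± 0.29) and sqt-3 (2.08 ± 0.21) rose and col-103 (-1.25 ± 0.13) fell in the authors' deposited table.

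Genes for ribosomal proteins and the protein genes of the mitochondrial genome were lower. Of 81 cytosolic ribosomal protein genes 55 were lower and none was higher (71 and 1 adjusted over the list alone), with a median log2 value of -0.41 (camera adjusted p = 3.7e-19) and rps-15 at -0.84 ± 0.12 and rpl-29 at -0.97 ± 0.14 in the authors' deposited table. After removal of the length trend 8 were lower and 1 was higher, with a median log2 value of -0.11 (camera adjusted p = 0.00300). Of 12 mitochondrial genome genes 10 were lower (11 adjusted over the list alone), with a median log2 value of -0.76 (camera adjusted p = 1.8e-14) and ctc-1, a cytochrome c oxidase subunit gene, at -1.12 ± 0.12 in the authors' deposited table. In all, 9 of the 24 lists passed the camera test, 4 of them higher and 5 lower. Adjusted over the list alone, the counts of the vitellogenin, early embryo, male soma, Argonaute, ERGO-1 target, intracellular pathogen response, heat shock and organelle stress lists were equal to those over all features.

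**Figure D2:**
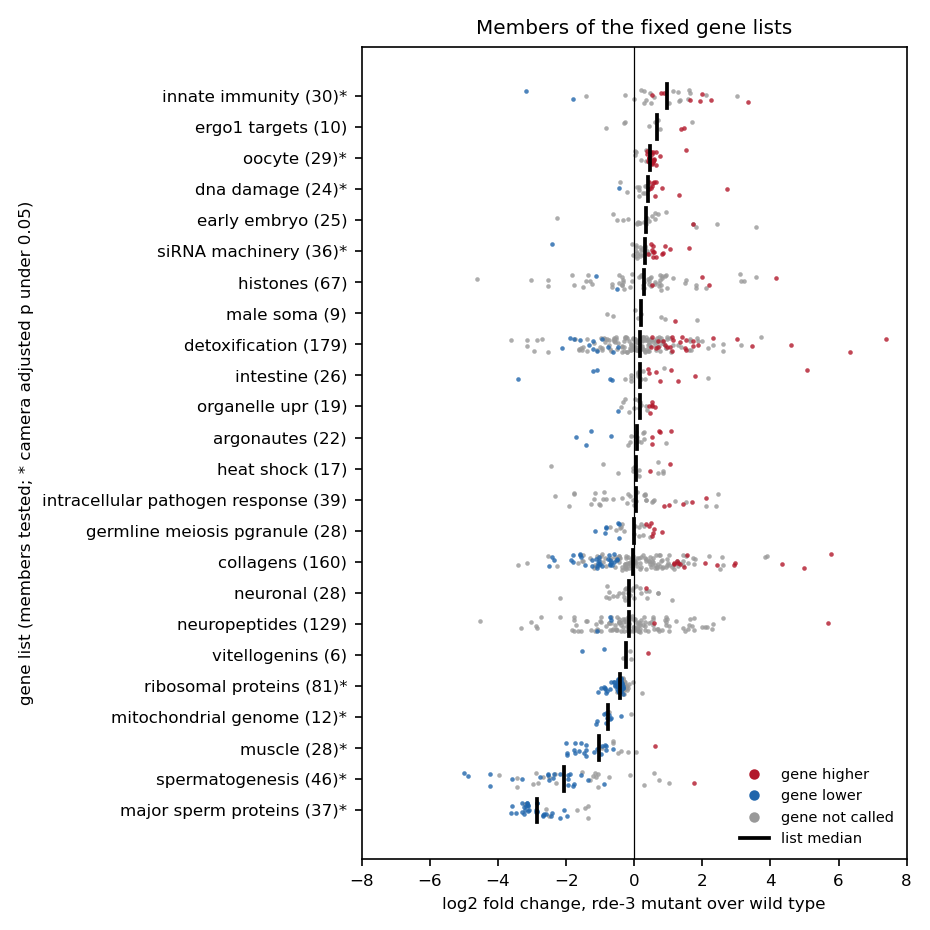
Log2 fold change (rde-3 mutant over wild type, horizontal axis) of each tested member of the 24 gene lists from the authors' deposited table, coloured by whether the gene was higher, lower or not called, with a black line at the list median and the number of members in brackets. Asterisks mark the 9 lists with a camera adjusted p under 0.05, and the major sperm protein list has the lowest median (-2.87); the medians of the Argonaute, germline, collagen and neuropeptide lists, none of which passed, change sign when the trend with transcript length is removed.

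Long genes were higher and short genes lower across the transcriptome. Across the 8912 genes with a mean normalized count of at least 50 and a known transcript length, Spearman's rho between log2 fold change and length was 0.315, where genes are not independent replicates. In the shortest decile (21 to 651 bp) 6.17% of genes were higher and 29.7% were lower, and in the longest decile (3479 to 45903 bp) 41.7% were higher and 6.95% were lower. A smooth fit of this trend, an added step chosen after seeing the data, was subtracted to see which lists moved with it. Afterwards 1267 genes were higher and 1213 were lower, of which 1115 and 1062 were among the genes called before. Ribosomal protein genes, with a median length of 520 bp, went from a median log2 of -0.41 to -0.11 and from 55 lower genes to 8, with 1 higher. The medians of the RNA interference list (0.31 to 0.15) and the DNA damage list (0.41 to 0.28) also shrank, while those of the major sperm proteins (-2.56), muscle genes (-1.18), oocyte genes (0.43) and innate immunity genes (1.21) stayed on their side, and each of these lists still passed. Of the lists that had not passed, counts moved by over 1.5 times for Argonautes (3 higher and 6 lower), germline genes (2 and 6), vitellogenins (0 and 4), histones (5 and 1), heat shock genes (1 and 0), neuronal genes (1 and 2) and neuropeptides (4 and 1). Under this subtraction the ERGO-1 targets (camera adjusted p = 0.0325, higher) and vitellogenins (0.000486, lower) passed as well. The mitochondrial protein genes were not matched by name to the annotation, so the check was not run on them, nor on the repeat classes.

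**Figure D3:**
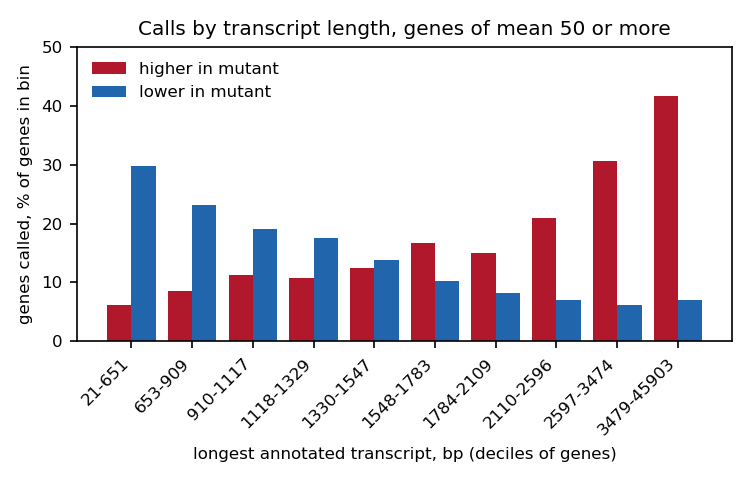
Percent of genes called higher (red) or lower (blue) in the rde-3 mutants (vertical axis) in each decile of 8912 genes ordered by the length of their longest annotated transcript in bp (horizontal axis), for genes with a mean normalized count of at least 50 in the authors' deposited table. The share of higher genes goes from 6.17% in the shortest decile to 41.7% in the longest, and that of lower genes from 29.7% to 6.95%.

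Genes on the X chromosome were higher less often than autosomal genes. Of 2563 X-linked genes 139 (5.42%) were higher, against 1582 of 15703 autosomal genes (10.1%), an odds ratio of 0.512 (Fisher's exact test, two-sided, p = 2.4e-15). Lower genes made up 181 (7.06%) of X-linked and 1295 (8.25%) of autosomal genes, an odds ratio of 0.845 (Fisher's exact test, two-sided, p = 0.0421), and of 0.781 (p = 0.00348) without the left end of X, a region chosen for its low values. The difference for higher genes was lost when a change of at least 2-fold was asked for (odds ratio 0.782, exact p = 0.0854), and the one for lower genes was lost at an adjusted p of 0.01 (odds ratio 0.890, exact p = 0.255). For lower genes the odds ratio lay on the other side of 1 with a change of at least 2-fold (1.014, exact p = 0.907) and without the length trend (1.099, exact p = 0.265).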

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

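The removal of the length trend and of the left end of chromosome X were chosen after the data were seen, and the other alternatives before. Counts of genes and repeats stayed within 1.5 times their value at an adjusted p of 0.1, with a minimum mean of 10, with separate adjustment, after recentring and, for genes, after removal of the length trend. After recentring 1461 genes were higher and 1729 were lower, so which direction held more genes depended on the centring. Lifting the low-count filter tested nothing, since the deposited adjustment already covers all features. At an adjusted p of 0.01 there were 990 lower genes, and with a change of at least 2-fold 530 higher and 631 lower genes and 1 lower repeat, by construction of the stricter thresholds. Against a t distribution with 2 degrees of freedom 0 genes and 0 repeats were higher and 0 and 0 were lower, the smallest adjusted p being 0.682. The unadjusted p was under 0.05 for 622 higher and 501 lower genes and for 12 and 2 repeats, where a share of 0.05 of 18638 unchanged features would be expected. The absence of adjusted calls follows from the heavy tails of that distribution over 18638 tests. No other tool was run.

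For X-linked against autosomal genes, the odds ratio for lower genes was 0.890 at an adjusted p of 0.01, 1.014 with a change of at least 2-fold and 1.099 without the length trend, the last 2 on the other side of 1, and 0.781 without the left end of X, further from 1 than the main 0.845, as the region was chosen for its low values; that for higher genes was 0.782 with a change of at least 2-fold; the cause was not tested. Of the sets, the ERGO-1 targets (adjusted p = 0.0325) and vitellogenins (0.000486) passed without the length trend, collagens (0.0271) with a minimum mean of 10, and satellites (0.0148) on ranks. The DNA class (0.0962) and Helitrons (0.0844) no longer passed at a correlation of 0.05, nor Helitrons (0.106) with a minimum mean of 10. The cause was not tested. Every other set kept its direction where called and its side of the threshold under the settings it was run with; the length trend was removed for 23 lists, not for the mitochondrial list or the repeat classes. Of the 94 named features other than mut-2, 2 no longer passed after recentring (vit-6 and unc-11) and 92 kept their side, 4 no longer passed without the length trend (vit-6, unc-11, hsf-1 and nlp-27) and 76 kept theirs, and 93 no longer passed against the t distribution. None reversed.

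No paired analysis was possible because the tables used hold no values per library. For the same reason the replicate block, a DESeq2 or edgeR fit and the fits without each replicate were not run. Depth limits the calls most at low means, where the median standard error of log2 was 0.608 for means of 10 to 100.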

Other observations

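The grouping of genes by name prefix, the collagen comparison, and the tests of the length trend on the sperm, muscle and oocyte genes, of somatic RNA, of embryos, of the left end of chromosome X, of neighbouring lower genes and of pairs transcribed away from each other were chosen after the results were seen. Among 146 name families with at least 10 members, tested with 292 one-sided Fisher's exact tests, 8 were rich in higher and 8 in lower genes. Without the length trend 2 of the higher families (asp and puf) and 6 of the lower ones still passed, while dpy, let, sel, pqn, cyp and klp were lost among the higher and rpl and rps among the lower, and skr and spp (higher) and unc (lower) passed as well. The acyl-CoA dehydrogenase family (acdh), whose enzymes act in fatty acid and branched-chain amino acid breakdown, had 6 of 13 members lower (adjusted p = 0.00712), and after removal of the length trend the adjusted p was 0.00353. In the authors' deposited table acdh-1 and acdh-2 had log2 values of -1.20 ± 0.13 and -1.95 ± 0.49. Genes for mitochondrial ribosomal proteins were also lower, 18 of 39 mrpl genes and 10 of 27 mrps genes, and 11 of 38 and 9 of 27 without the length trend. The collagen family col had 32 of 141 members lower (Fisher's exact test, adjusted p = 3.5e-06) and 8 higher. Without the length trend 28 were lower (Fisher's exact test, adjusted p = 1.1e-05) and 9 were higher. The puf family of RNA-binding proteins had 6 of 10 members higher (adjusted p = 0.00302, and 0.00106 without the length trend). The kinesin family (klp) had 8 of 14 members higher (adjusted p = 0.000449) but 2 of 14 without the length trend.

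The cuticle collagens that rose and those that fell differed in abundance. The 14 higher collagens had a median mean normalized count of 82.7 and the 32 lower ones 6394 (permutation test of medians, two-sided, p = 2.0e-05, the smallest these permutations can give). Both groups were formed by the calls, and small changes can be called only in abundant genes, so abundance partly decides who enters them. The permutation also treats related genes as independent, so its p does not measure the spread between animals. In the authors' deposited table the rare ones included dpy-14 (log2 4.34 ± 0.68), dpy-7 (2.94 ± 0.70) and dpy-2 (2.43 ± 0.54), which act in body shape, and the abundant ones included the adult collagen gene col-19 (-1.12 ± 0.13). The cuticlin gene cut-3 rose with them (log2 5.54 ± 0.58) in the authors' deposited table. The Argonaute genes alg-3 and alg-4, which act in spermatogenesis, had log2 values of -1.72 ± 0.36 and -1.42 ± 0.32 in the authors' deposited table, beside the sperm genes. These genes were named after their values were seen.

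Long genes were higher and short genes lower in the mutants. The makeup of the fixed lists does not account for this, since rho was 0.314 among 8331 genes in no list, and low counts do not, since rho was 0.427 among 2817 genes with a mean of at least 1000. A length-dependent difference in RNA quality or library preparation would act within functional groups too, and within 18 lists rho was 0.184 over 554 genes (permutation p = 0.0001, the smallest these permutations can give). A biological preference for long genes would act within lists as well, so this value cannot tell it from a technical cause. The permutation p treats the genes of a list as independent and does not measure the spread between animals. A technical cause may also be confounded with genotype, because each group has 2 libraries with no values of their own here. A biological preference for long genes in the mutants was not tested and stays open.

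Sperm and muscle genes were lower and oocyte genes higher. The length trend is not the whole cause, since medians without it were -2.56 for the major sperm proteins, -1.18 for muscle and 0.43 for oocyte genes, with interquartile ranges on the same side of 0. A lower share of all somatic RNA would lower neuronal and intestine genes alike, but the muscle median differed from theirs by -1.07 on the log2 scale (permutation test, two-sided, p = 2.0e-05, the smallest these permutations can give). This permutation and the bootstrap that follows treat genes as independent, so neither measures the spread between animals. The values of these lists were known when the permutation test was chosen. Whether the mutant animals held more embryos cannot be told apart: the 10 early zygotic genes with a mean of at least 50 had a median of 0.33 (95% bootstrap interval 0.134 to 0.524), and their list did not pass (camera adjusted p = 0.306). That list was drawn up for early zygotic genes, so later embryonic stages were not tested. The risen cuticle genes, such as dpy-17 and sqt-3, were not weighed in it. A difference in age or in sperm number between the cultures, or an effect of rde-3 itself, could give the same values and was not tested.

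Strongly changed genes lay next to each other, with 18 neighbouring pairs of protein-coding genes with both members higher by log2 of at least 2. Random placement gave 2.36 expected and at most 10 in 10000 placements. For pairs with both lower the number was 32, against 3.99 expected and at most 14. Both numbers exceeded all random placements, which take no account of clusters of related genes. Many lower pairs held sperm genes (such as msp-57 and msp-53) or pud genes (pud-3 and pud-4). The higher pairs included cyp-13A6 and cyp-13A7. The numbers thus partly restate the changes of such families and do not show an effect of position. For the lower pairs read-through and shared operons are not the whole cause, since 21.9% lay on one strand against 52.5% of all neighbouring pairs (Fisher's exact test, two-sided, p = 0.000554) and 16 were transcribed away from each other without overlap, against 0.863 expected and at most 6. For the higher pairs they cannot be told apart from other causes, as 61.1% lay on one strand (Fisher's exact p = 0.491) and 3 were transcribed away from each other without overlap, against 0.518 expected and at most 5. At the left end of chromosome X, up to the gene set-28 (end at 215588), where the low values ended and which was chosen for that reason, the 14 features with a mean of at least 10 had a median log2 of -2.56, which partly restates this choice. A lost segment in the mutant strain may account for these values, but the 5 features with means of at least 50 ranged from -5.92 to -1.26, so some reads remained, and reads shared with copies elsewhere were not examined.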
